A study of Mus musculus with 15 samples.

How the data were processed

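DNA came from pellets of about 10000 HSCs per sample from the bone marrow of old mice and from the tail of each mouse, per the labels' protocols. Exome capture and paired-end sequencing were done by either of 2 services, to a planned coverage of 150 for HSC DNA and 30 for tail DNA. Which service handled which mouse is not given in the sources used here, so a batch by service could not be examined. Bowtie2 is named in the submitters' processing notes. Each HSC library was called against the tail library of the same mouse, per the file headers, with Mutect2, per the name of the deposited calls. Gene annotation columns are those of refGene, per the file headers. The caller's version, its filters and the genome build are not given in the sources used here. As a check of names, 30 of 30 sites with values lay inside the span of the gene of the same name on GRCm38.p6; the coordinates printed are those of the call lists.

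The deposited lists give, per call and library, the read depth at the site as counts of reads, per the file headers. They give the alternate allele fraction of the HSC and tail libraries, per the file headers. This fraction is the caller's estimate, since depth times fraction came out whole, within the rounding of the fraction, in 7 of 44 entries. The deposited call quality is a score whose scale is not stated. A summary by the authors sorts the calls of each mouse into AThi only, ATlo only and both, and was checked against the lists: 31 of 31 calls with values had the same place, and the tallies of 5 of 5 mice were equal. One shared call of mouse 2, in 2 of 46 entries, has values not analysed here, and neither it nor 1 further call is reported here by name. The first enters the counts of calls and of classes, but not the allele fractions, and the further call enters all counts and tests. The lists hold calls only, so total depth, covered bases and reads at sites without a call were not used here.

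Samples were grouped by the autophagy status and the mouse number in the labels. AThi and ATlo libraries of a number come from the same animal, per the labels and the stated design, so the mouse was the pair. Calls per library and the median allele fraction were compared by an exact paired permutation test over all sign flips, two-sided, with an unpaired permutation as an alternative. Alternate reads were estimated as depth times fraction, rounded. For each shared call these and the remaining reads were compared between fractions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 calls and a threshold of 0.05. A Newcombe interval was given for the difference. AThi-only against ATlo-only counts were compared by an exact binomial test, and transitions and consequence classes by Fisher's exact test on calls in a single fraction. These tests pool calls over mice as independent and do not measure the spread between mice. Substitutions were folded into 6 pyrimidine classes. Shares have exact Clopper-Pearson intervals and fractions have Wilson intervals at 95%. Reads without molecular identifiers are not independent molecules, so these cover counting error only. Single-fraction and shared calls were compared in fraction, quality and depth by permutation tests with 100000 resamples, and in transitions, T>G and intronic calls by Fisher's exact test, with these 6 adjusted together. Permutations within mice were not adjusted. For a shared call these took the mean fraction and depth of both libraries and the lower quality.

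The comparisons, the tests, the gene lists and the rule for named genes were set before the data were examined, except where stated. The rule names genes of the fixed lists, genes passing the test per call, the 20 genes with the highest allele fraction and at least the top 2 of each mouse, and genes called in at least 2 mice. It named 23 of 30 genes; Capza1, Kif15, Rgs16, Robo4, Slc24a2, Tmem67 and Tspyl2 were added after their values were seen. Alternatives were minimums of 3 or 5 estimated alternate reads, fractions of 0.02, 0.05 or 0.1 and depths of 20 or 50. Others were substitutions only, no estimated alternate read in tail, no site called in 2 mice, no gene prone to false calls, protein-altering calls only, and each mouse left out. The depth minimums applied to the library of the call alone.

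The test per call was tested on simulated data with the real depths of the 13 shared calls, 1000 times. With no difference, 4.4% of the simulations gave a call at the adjusted threshold. With fractions of 0.5 against 0.25, 82.9% of calls were found, and with 0.5 against 0.35, 39.6%. In these simulations all 13 calls were given the same difference, including those on chromosome X, which stood higher in the data. The shares therefore do not give the chance of finding a difference in a single call. The software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.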

Results

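Whole-exome sequencing was used to compare somatic mutations between autophagy-engaging and non-engaging haematopoietic stem cells (HSCs) of old mice. The mice carried Gfp-Lc3, a fusion of green fluorescent protein to the autophagosome protein LC3, whose signal falls as autophagy proceeds. HSCs with low signal were sorted as AThi and HSCs with high signal as ATlo. Each of 5 mice gave an AThi library, an ATlo library and a tail library for the germline baseline, 15 libraries in all. The stated design has 6 pairs, while the samples used here come from 5 mice. The call lists held 32 somatic calls, of which 31 had values, in 23 AThi and 21 ATlo entries. At these entries the median depth was 72 reads in HSC DNA (range 13 to 371, planned coverage 150) and 54 reads in tail DNA (range 10 to 280, planned 30). Median HSC depth at the called sites was 92.5 reads in AThi and 92 in ATlo of mouse 1, 85 and 152 in mouse 2, 29.5 and 35 in mouse 4, and 22.5 and 19.5 in mouse 5. The ATlo library of mouse 3 had a median of 75 reads, and its AThi library had no call. Allele fractions are given with the depth and a 95% Wilson interval where they stand alone. These intervals cover counting error only.

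The first question was whether the mutation burden differed between the fractions. In mouse 1, calls in Capza1, which encodes an actin-capping subunit, and in the ciliary gene Tmem67 were made only in AThi cells, and no call was made only in ATlo cells. In mouse 3 the position was reversed, with calls in Mdm2, which encodes the main ubiquitin ligase acting on Trp53, in the endosomal sorting gene Vps37b and in Tspyl2 in ATlo cells and none in AThi cells. Mouse 5 had Dgka and Rgs16 in AThi cells and Crlf2 and Terf2 in ATlo cells. Capza1, Tmem67, Tspyl2 and Rgs16 fell outside the rule for named genes and were chosen after their values were seen. The authors' deposited table counted 8 calls in AThi and 6 in ATlo of mouse 1, 8 and 4 in mouse 2, 0 and 3 in mouse 3, 6 and 7 in mouse 4, and 2 and 2 in mouse 5. Counted by library, AThi cells had 4.8 ± 3.63 calls (SD, n = 5) and ATlo cells 4.4 ± 2.07 (SD, n = 5). The mean difference of 0.4 calls was below the SD of the paired differences, 2.70, with AThi higher in 2 mice, ATlo higher in 2 and both equal in 1 (two-sided exact paired permutation p = 0.875). With 5 pairs the smallest p this test allows is 0.063. The difference was -0.5 calls without mouse 2, 0 without mouse 1, 0.75 without mouse 4 and 1.25 without mouse 3, and the number of exome bases covered in each library was not used here.

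**Figure D1:**
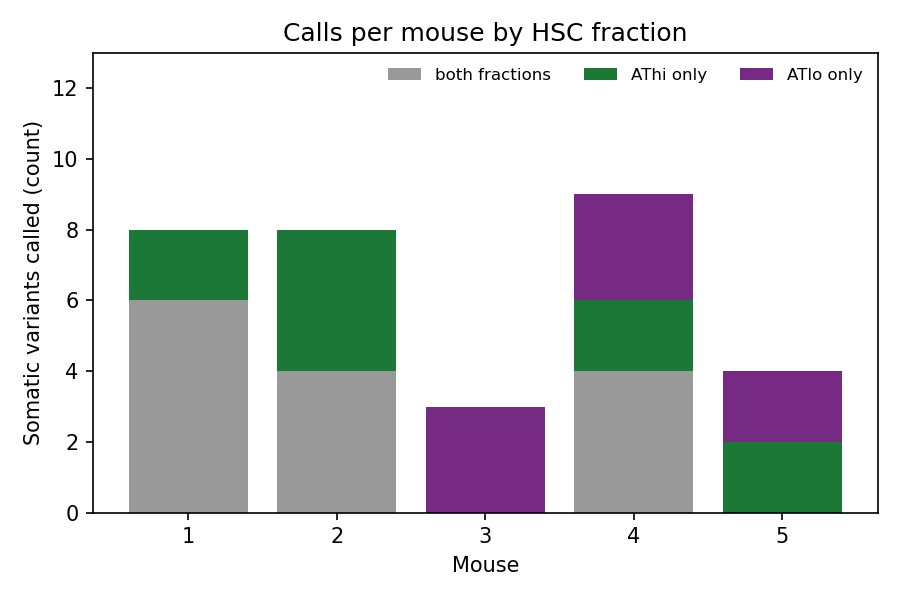
Somatic variants called per mouse (bars, count), stacked as calls in both fractions (grey), in AThi only (green) and in ATlo only (purple). Mice 1 and 2 had 2 and 4 calls only in AThi, mouse 3 had 3 calls only in ATlo, mouse 4 had calls of each kind and mouse 5 had 2 only in AThi and 2 only in ATlo.

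The second question was whether the fractions differed in their clones. All 3 shared calls on chromosome X stood at high allele fractions in both fractions. They were an A299V substitution in Shroom2, which encodes an actin-binding protein, in mice 1 and 4, and a synonymous substitution in the homeobox gene Rhox2e in mouse 1. Shroom2 stood at 0.943 in AThi and 0.98 in ATlo of mouse 1, and at 0.863 and 0.998 in mouse 4; Rhox2e stood at 0.972 and 0.976. The 10 autosomal shared calls lay between 0.167 and 0.586, and 1 of them differed from 0.5 with both libraries pooled, as given below. Inherited variants with tail DNA from another animal would also put autosomal calls near 0.5 and, in males, X calls near 1. The sex of the mice was not examined here, and in females a heterozygous inherited X variant would lie near 0.5. Inherited variants would have equal fractions in AThi and ATlo cells whatever the clones, so similar fractions need not reflect clones. In mouse 2, the V161M substitution in the sodium channel gene Scn8a had 0.518 in AThi and 0.525 in ATlo, and the G612X stop in the protocadherin gene Pcdhb5 had 0.479 and 0.491. In mouse 4, an intronic call in the collagen gene Col5a2 had 0.488 and 0.538, and I127V in the cytochrome P450 gene Cyp2j6 had 0.449 and 0.474. In mouse 1, a synonymous call in the histone reader gene Zmynd11 had 0.461 and 0.426, and an intronic call in the adhesion gene Bcam had 0.424 and 0.34. The D577N substitution in Robo4, a roundabout receptor gene chosen after its values were seen, stood lowest, at 0.174 and 0.167.

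The largest difference was in Eml2, which encodes a microtubule-associated protein. Its intronic call in mouse 2 had a fraction of 0.348 at 73 reads in AThi and 0.586 at 57 reads in ATlo, a difference of -0.238 (95% Newcombe interval -0.391 to -0.0640). Rapgef3, which encodes a cAMP-activated exchange factor, carried P580L at 0.505 of 109 reads in AThi and 0.356 of 99 reads in ATlo of mouse 1. None of the 13 shared calls passed Fisher's exact test at a Benjamini-Hochberg adjusted p under 0.05. Eml2 had p = 0.00814 (adjusted 0.106), Shroom2 in mouse 4 had p = 0.0344 (adjusted 0.154) and Rapgef3 had p = 0.0355 (adjusted 0.154), all by Fisher's exact test. Those with an unadjusted p under 0.05 numbered 3 by Fisher's exact test and 2 by a chi-squared test with continuity correction. The fraction was higher in AThi for 5 calls and higher in ATlo for 8, with a median absolute difference of 0.037. Adjusted within each mouse in place of over all calls, 1 call passed Fisher's exact test, Eml2 (adjusted p = 0.0244, over a range of 0.0244 to 0.155 in its alternatives). Each test compares 2 libraries of a mouse and has no replicate behind it, and the intervals of the differences reached 0.0363 to 0.222 to either side.

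**Figure D2:**
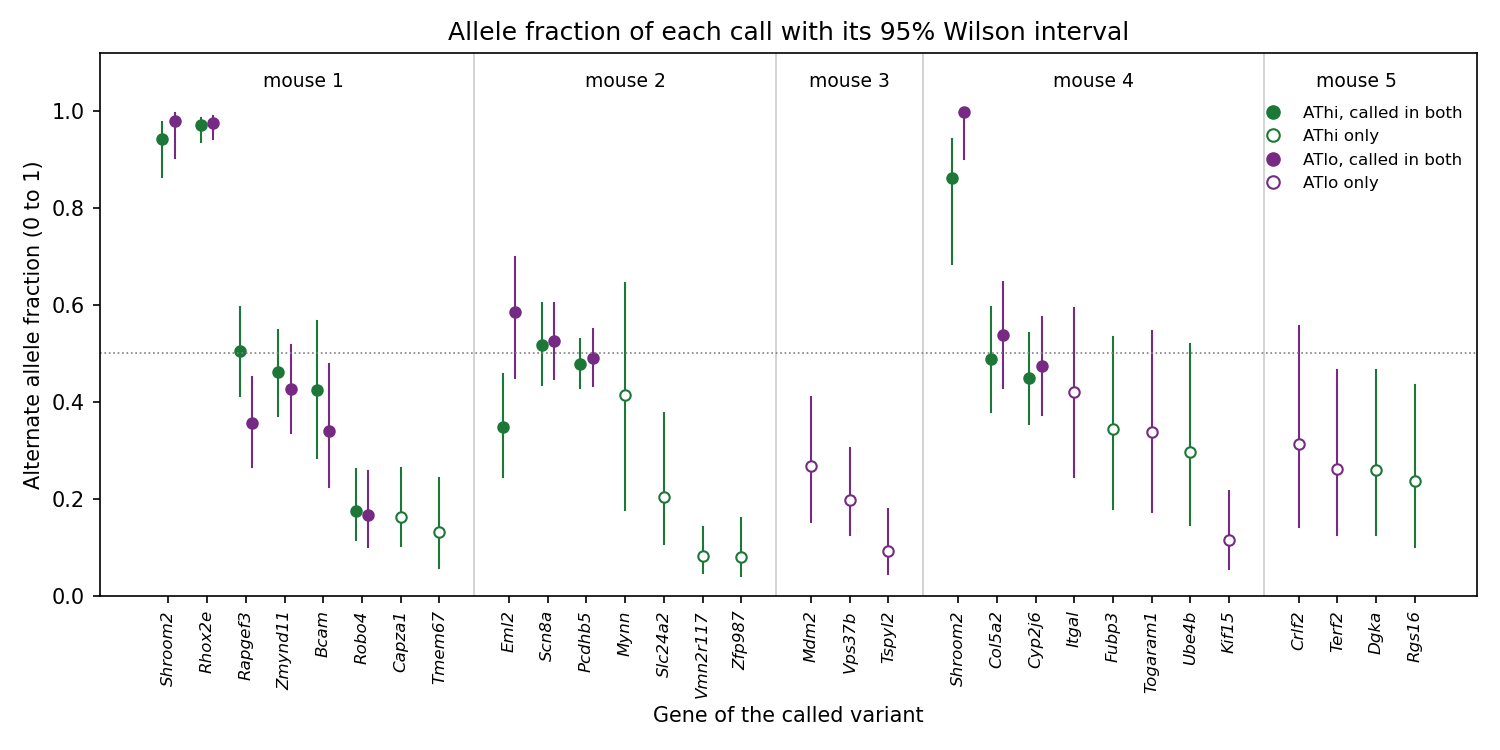
Alternate allele fraction (0 to 1, y axis) of 30 of the 31 calls with values, by gene and mouse (x axis), for AThi (green) and ATlo (purple). Filled points were called in both fractions and open points in 1; bars are 95% Wilson intervals, and the dotted line marks 0.5. Open points lie at or below 0.42, and Shroom2 and Rhox2e lie at 0.863 or above.

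Calls in a single fraction fell on both sides. In AThi cells they were in Capza1, Tmem67, Vmn2r117, Mynn, Zfp987, Slc24a2, Fubp3, Ube4b, Dgka and Rgs16, of which Slc24a2 was also chosen after its values were seen. In ATlo cells they were in Mdm2, Vps37b, Tspyl2, Togaram1, Itgal, Kif15, Crlf2 and Terf2, of which Kif15 was likewise chosen afterwards. The highest fractions were 0.42 for a deletion in an intron of the leukocyte integrin gene Itgal in ATlo cells (27 reads, interval 0.245 to 0.593) and 0.415 for an insertion in an intron of the zinc finger gene Mynn in AThi cells (13 reads, interval 0.177 to 0.645). Mdm2 had 0.267 at 42 reads (interval 0.153 to 0.411), and Terf2, which encodes a telomere-binding protein, had 0.261 at 23 reads (interval 0.125 to 0.465). Crlf2, which encodes a cytokine receptor subunit, carried R345M at 0.313 of 16 reads (interval 0.142 to 0.556). AThi-only calls were 10 of the 18, or 55.6% (exact 95% interval 30.8 to 78.5%), and did not differ from an even split (two-sided exact binomial p = 0.815). The test and interval pool calls over mice as independent and do not measure the spread between mice. The AThi-only share was 42.9% without mouse 2 and 50% without mouse 1. By the authors' deposited table, 14 of 32 calls, or 43.8%, were in both fractions: 6 in mouse 1, 4 in mouse 2, 4 in mouse 4, and 0 in mice 3 and 5. The share was 25% with no estimated alternate read in tail and 61.5% for protein-altering calls. For a call in a single fraction the lists give no depth or fraction for the other library, so its absence there was not measured.

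The median allele fraction per library was compared next, over autosomal and X calls together, which in males do not share a scale of clone size. In mouse 2 it was 0.348 in AThi cells, the value of Eml2, and 0.525 in ATlo cells, the value of Scn8a. It was 0.4425 and 0.391 in mouse 1, 0.4685 and 0.42 in mouse 4, and 0.2485 and 0.287 in mouse 5. The mean was 0.377 ± 0.10 in AThi (SD, n = 4) and 0.406 ± 0.0979 in ATlo (SD, n = 4). The difference of -0.0289 was below the SD of the paired differences, 0.107 (two-sided exact paired permutation p = 0.875, where 4 pairs allow a smallest p of 0.125). With the mean of each library in place of the median the difference was -0.0753 (exact paired permutation p = 0.25). With the maximum it was -0.066, with ATlo higher in 4 of 4 mice, although the maxima of mice 1 and 4 are the X calls in Rhox2e and Shroom2 (exact paired permutation p = 0.125, the smallest possible). The median difference changed sign without mouse 2 (0.0205) and over calls in both fractions (0.014), a setting added after the data were seen. It also changed sign with no estimated alternate read in tail (0.152), without genes prone to false calls (0.003) and with 0 where not called (0.0475). The difference was -0.0557 without mouse 1, -0.0547 without mouse 4, -0.0576 for substitutions only and -0.0121 at a fraction of at least 0.1.

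The kinds of mutation were then compared. The sites, in the coordinates of the call lists, whose genome build is not given in the sources used here, were as follows for 6 sites of protein-altering shared calls, with Shroom2 called in 2 mice. Rapgef3 P580L lay in exon 18 at position 97753872 of chromosome 15, and Robo4 D577N in exon 12 at position 37408184 of chromosome 9. Shroom2 A299V lay in exon 5 at position 152613618 of chromosome X, and Scn8a V161M in exon 3 at position 100957114 of chromosome 15. Pcdhb5 G612X lay in exon 1 at position 37322402 of chromosome 18, and Cyp2j6 I127V in exon 3 at position 96536140 of chromosome 4. Exon and residue numbers are those of the transcript listed first. The splice-region call in Mdm2, at position 117701622 of chromosome 10, lay 8 bases from the exon. Transitions were 3 of 8 substitutions in AThi only (Capza1, Tmem67 and Fubp3) and 2 of 6 in ATlo only (Mdm2 and Vps37b), a difference of 4.17 percentage points (two-sided Fisher's exact p = 1). That difference changed sign without mouse 1 (-16.7 points), mouse 4 (-6.67) or mouse 5 (-7.14), and was 26.7 points without mouse 2 and 37.5 without mouse 3. Among the 13 shared calls, 11 were transitions, 9 of them C>T. Protein-altering or splice-region calls were 3 of 10 in AThi only (Vmn2r117, Zfp987 and Rgs16) and 2 of 8 in ATlo only (Mdm2 and Crlf2), a difference of 5 percentage points (two-sided Fisher's exact p = 1). It changed sign without mouse 2 (-8.33 points), without mouse 4 (-2.5) and without genes prone to false calls (-12.5), and was 12.5 points without mouse 1, 10 without mouse 3 and 8.33 without mouse 5. By the authors' deposited table, such calls were 9 of the 14 shared calls, and 15 of all 32 calls were intronic.

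Gene lists fixed before the data were examined were then searched. Of the 32 calls, 0 lay in 60 genes recurrently mutated in clonal haematopoiesis, such as Dnmt3a and Tet2, and 0 in 58 autophagy genes. Likewise 0 lay in 51 DNA repair genes, 0 in 33 HSC genes, and 0 in the lymphoid receptor loci. The last count is not a check for lymphocyte DNA, as rearrangements of these loci were not examined. In the list of large or repeated genes prone to false calls there were 3, Vmn2r117 at 0.082 and Zfp987 at 0.079 in AThi cells of mouse 2, and Cyp2j6 in both fractions of mouse 4. Vmn2r117, Zfp987, Rhox2e and Pcdhb5 belong to gene families with similar copies; whether reads of other copies were aligned at these sites was not tested. Which genes of each list were covered was not analysed here, and no enrichment was tested.

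Shroom2 was the only one of 31 genes called in at least 2 mice, in both cases as the same substitution. No gene was called in more than a single mouse without mouse 1 or without mouse 4, where the count was 0. In tail DNA, Shroom2 had a fraction of 0.012 in mouse 1 and 0.002 in mouse 4. Over all entries, the estimated tail fraction was above 0 in 43 of 44 (97.7%, exact 95% interval 88.0 to 99.9%), with a median of 0.0155 and a highest value of 0.062, in Fubp3. Each of the 13 shared calls with values counts in 2 entries against the same tail library. The entries are thus not independent, and the interval is too narrow. A fraction above 0 is the caller's estimate and need not mean an alternate read. At least 1 estimated alternate read stood in tail for 34 entries (77.3%), at least 2 for 12 (27.3%), the largest being 11 of 280 reads for Pcdhb5, and a fraction of at least 0.02 for 17 (38.6%).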

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

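The added settings named here were chosen after the data were seen. The AThi minus ATlo difference in calls was -0.2 at a depth of at least 50, 0 with no estimated alternate read in tail and 0 without genes prone to false calls, and ran from -0.5 to 1.25 with each mouse left out. For median allele fraction it was 0.152 with no tail read (2 mice), 0.003 without prone genes, 0.0475 with 0 where not called and, added, 0.014 for calls in both fractions, and ran from -0.0557 to 0.0205. AThi-only calls were 42.9% at a depth of at least 50, 50% with no tail read and 50% without prone genes, and ran from 42.9 to 66.7%. Calls in both were 25% with no tail read. The depth and tail filters acted per library, so a shared call losing a library was recounted as a single-fraction call. At a depth of at least 50, Bcam (43 reads in AThi, 50 in ATlo) was recounted as ATlo only. This entered both the 42.9% and the difference of -0.2 calls. With no tail read, Cyp2j6 was recounted as AThi only, its tail estimate being 0 reads in the AThi entry and 1 in the ATlo entry. Adjustment within each mouse gave 1 call with a fraction difference; leaving out any mouse gave 0. The transition difference ran from -16.7 to 37.5 points. The consequence difference was -12.5 points without prone genes and ran from -8.33 to 12.5. Genes called in several mice ran from 0 to 1. Entries with tail signal were 77.3% (added), 27.3% and 38.6% under the read and fraction minimums, and ran from 96.8 to 100%. No replicate block, in place of the paired test, gave exact permutation p = 0.905 for calls (0.4) and 0.714 for median fraction (-0.0289); the paired tests of these values cannot reach 0.05, so this says nothing about stability. Beyond the recounted calls and smaller counts under stricter minimums, the cause of these shifts was not tested. Direction was kept in 14 of 19 settings for calls, 18 of 23 for median fraction and 13 of 18 for AThi-only share. The count of differing fractions was kept in 20 of 21. Several of these settings could not change a result, so the tallies do not measure stability. The minimums of estimated alternate reads and the fraction minimums of 0.02 and 0.05 removed no call with values. The lowest HSC fraction was 0.079, and no HSC estimate was below 5 alternate reads. The unpaired test keeps the difference by construction. Leaving out the site called in 2 mice removed as many AThi as ATlo calls. Holm adjustment cannot pass more calls than Benjamini-Hochberg. A filter column was not used here. Depths of 13 to 371 limit small fractions.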

Other observations

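All tests in this part were chosen after the results were seen. Calls made in a single fraction were set beside calls made in both. A site with a low fraction or depth is less easily called in both libraries. The grouping by itself therefore tends to give lower values, to an extent that was not measured. The 18 single-fraction calls, such as Dgka, Mdm2 and Terf2, had a median allele fraction of 0.2485, against 0.467 for the 13 shared calls with values, such as Scn8a, Col5a2 and Cyp2j6 (permutation p = 1e-05, the smallest the resamples can give, adjusted 3e-05). Within mice 1, 2 and 4, which have both kinds, the medians were 0.203 and 0.467 (permutation p = 0.00286). Median HSC depth was 30 against 93.5 reads (permutation p = 0.00191, adjusted 0.00382; within mice p = 0.0298). Intronic calls were 12 of 18 against 3 of 14 (Fisher's exact p = 0.0155, adjusted 0.0220; within-mouse permutation p = 0.0086). T>G substitutions, found in Zfp987, Slc24a2, Tspyl2, Dgka and Terf2, were 5 of 14 against 0 of 13 (Fisher's exact p = 0.0407, adjusted 0.0407). The permutation within mice 1, 2 and 4 gave p = 0.400, over only 8 and 13 substitutions. It left out Tspyl2, Dgka and Terf2, which were called in mice 3 and 5, so it does not show that the difference goes away within mice.

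Median call quality was 13.85 for single-fraction calls and 112.3 for shared calls (permutation p = 1e-05, the smallest possible, adjusted 3e-05; within mice 1, 2 and 4 p = 0.0206). Of the 18 single-fraction calls, 17 had a quality below 24.7, the lowest among shared calls, and Vmn2r117 at 31.8 was the exception. This restates the pattern and does not decide whether calls near the detection limit fell on either side by chance. Sequencing or alignment errors stay open too, as transitions were 5 of 14 against 11 of 13 (Fisher's exact p = 0.0183, adjusted 0.0220). The permutation within mice 1, 2 and 4 gave p = 0.113, over only 8 and 13 substitutions. Clones confined to AThi or ATlo cells also stay open: for 0 of the 18 calls do the lists give a depth and fraction in the other library of the mouse, so these explanations cannot be told apart.

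The Shroom2 A299V call, at 0.863 to 0.998 in 4 HSC libraries of mice 1 and 4, may reflect several causes. Mixing of DNA or reads between the 2 mice is argued against, since 0 of their 8 other shared calls, Rhox2e and Col5a2 among them, was called in the other mouse. An alignment or sequencing error common to all libraries would put the tail fraction near the HSC fraction. In tail DNA the highest fraction was 0.012, with an exact (Clopper-Pearson) 95% upper bound of 0.0989 against an exact lower bound of 0.673 in HSC DNA. A low tail fraction is a condition of being called, so this gap was largely fixed by the calling. It does not decide between errors, common to all libraries or confined to HSC libraries, and other causes. Inherited variants with tail DNA from another animal, and a clone that holds nearly all HSCs, would each put Shroom2 near 1 in males. The sex of the mice was not examined here. The autosomal shared calls cannot tell these explanations apart, because both put such calls near 0.5. Of 10 such calls, 1 differed from 0.5 in the pooled fractions, Robo4 at 0.171 (exact binomial adjusted p = 1.46e-19), which neither would give if it covered every call of mouse 1. Clones would also need the same Shroom2 substitution to arise separately in mice 1 and 4, which the autosomal fractions do not address.

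The planned coverage ratio of HSC to tail DNA was 5, and the ratio of depths at the called sites had a median of 1.10 (range 0.651 to 4.2). A dbSNP entry was given in 1 of 44 entries, for Bcam in ATlo cells of mouse 1, and not for the same site in AThi cells.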
